A study of Mus musculus with 4 samples.

How the data were processed

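RNA-seq was run on total RNA of 4 samples of the C8-D1A line, 2 untreated and 2 treated. Per the labels' protocols, ribosomal RNA was depleted and libraries were made with a directional kit, which marks the strand. The submitters' processing notes name bcl2fastq, HISAT2 and the GRCm38 genome. Their versions, the counting program, the gene annotation and whether counting used strand are not given in the sources used here. The authors deposited 1 table of FPKM (fragments per kilobase of gene and fixed number of mapped reads) for 24169 genes, with symbols, biotypes, positions and GO terms per gene. Without stranded counting, reads of overlapping genes cannot be told apart.

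Columns were matched to samples by title. Replicates were numbered 1 and 2 within a group in accession order, and the number pairs nothing. Spreadsheet software had turned 24 symbols into dates, and these were restored from gene identifiers. GENCODE mouse release 21 held 24121 of the identifiers, 22424 of them with the same coordinates, and gave exon length, transcript length and GC content of the longest transcript. Coordinates in the text are those of the deposited table (GRCm38).

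FPKM is not a count. For 6079 single-exon genes the deposited FPKM times length fell on whole multiples of 1 step per library, which is what 1 read is worth. At least 99.95% of these values under 1000 reads were whole within 0.05, and 93.8% to 94.0% of values of all genes. Depth from this step was 23571000 to 25907000 reads. Intervals in the text are limma's, from the spread between libraries. Read numbers are not numbers of independent molecules, since no molecular identifiers are described.

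Values were tested as log2(FPKM + 1), so fold changes are on that scale and understate the change of low genes. Genes with FPKM of at least 1 in at least 2 of the 4 samples entered (12403). The test was two-sided and used limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a trend), MBP minus control, with Benjamini-Hochberg adjustment and a threshold of 0.05. There were 27 gene lists fixed before the data were examined, 26 of them with at least 3 tested genes. They were tested with camera at a preset correlation of 0.01, adjusted over the lists, with camera at an estimated correlation and fry beside it. At the preset correlation, camera takes its degrees of freedom from the number of genes, so its p does not reflect how few libraries there are. With an estimated correlation, camera takes its p from the 2 residual degrees of freedom of the 4 libraries, so it has little power here. Fry's directional test asks whether a list's genes move on balance one way and its mixed test whether they change in either direction. Listed genes absent from the table were not analysed here.

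The rule for named genes was also fixed before the data were examined. It takes the genes of the title and Gfap whatever their test, and from each list up to 4 members with the lowest adjusted p. It also takes the 12 largest rises and falls past the threshold. Because fewer than 24 genes passed, these were ranked by unadjusted p and are given as values. They need groups that do not overlap, a mean FPKM of at least 5 in the higher group, and a symbol that is not a predicted gene, RIKEN clone, pseudogene or mitochondrial or ribosomal RNA. Of the genes this rule takes, 3 are not reported here. Other list members, and the genes that single alternatives called, were named after their values were seen.

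The gene test was checked on simulated data, 20 simulations of 12389 genes with 200 changed. It recovered 45.2% of genes changed 1.5-fold, 81.0% of those changed 2-fold and 97.8% of those changed 4-fold. Among 3151 calls 5.4% were false, slightly above the nominal 5%. The adjustment depends on how many genes change, so these shares hold for 200 changed genes of these folds. With fewer or smaller changes a gene of the same fold would be recovered less often, so they do not give the power of the main test. The list test was checked in 20 separate simulations with a planted GC slope, on values after the GC and length correction described below. A list planted at a log2 change of -0.3 was called in 20 of 20 and unchanged lists in 1 of 520 tests. The main list test, on uncorrected values, was not simulated. Genes in the simulations vary independently, so the list result does not cover correlated genes.

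Alternatives fixed before the data were examined were pseudocounts of 0.1 and 0.01, no filter, a filter of 5, TPM, median-of-ratios scaling, quantile normalization, no spread trend, a robust spread, no moderation, each library left out, protein-coding genes only, and a fold threshold. After the data were seen, 6 more were added: a loess correction (span 0.5) for GC content and length, the same on protein-coding genes, the spread trend on recovered reads with all or protein-coding genes, and limma-voom on recovered reads of genes with a mean of at least 10 reads or of protein-coding genes with at least 50. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.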

Results

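RNA was profiled in C8-D1A cells, an established mouse astrocyte line, that were left untreated (2 libraries) or kept for 24 h in 1 mM MBP (2 libraries). The series title concerns maternal exposure to DBP, dibutyl phthalate, a plasticizer whose main metabolite is monobutyl phthalate, and names AKT, NF-κB, IL-6, JAK2 and STAT3 signalling, astrocyte activation and synapse formation. The labels give the treatment only as MBP, which here is a compound and not the gene Mbp. Library depth, recovered from the step size of the deposited values, was 24349000 reads for control 1, 23571000 for control 2, 23954000 for MBP 1 and 25907000 for MBP 2, rounded. Nothing in the labels says that the libraries of a group came from separate cultures. P-values therefore measure the spread between these samples, which may be technical. The exception is camera at the preset correlation, whose p takes genes as the units and does not measure how a list varies between libraries.

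The first question was how far the 2 groups lay apart. The libraries of a group were about as far from each other as from the other group. The root mean square difference of log2(FPKM + 1) over 12403 genes was 0.235 between the 2 controls and 0.209 between the 2 MBP libraries. Between groups it ran from 0.215 for control 1 against MBP 2 to 0.265 for control 2 against MBP 1. The mean between groups was 1.06 times the mean within groups. Pearson correlations across genes, which are not independent replicates, lay between 0.985 and 0.990. The first principal component held 45.5% of the variance and set control 2 (score 17.3) against MBP 1 (score -11.2), with control 1 near 0 at -0.417. A comparison of 2 against 2 libraries allows no exact p under 0.333, so no test was made of these distances.

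The main comparison asked which genes differed between MBP-treated and untreated cells. The 12 genes with lower values in MBP and the lowest unadjusted p had folds of 0.649 to 0.785, computed from log2(FPKM + 1). They included the protein-folding helpers Sdf2l1, Creld2, Manf and Hyou1 of the endoplasmic reticulum. The 12 with higher values included 5 small non-coding RNA genes. None of these differences passed the test: no gene reached an adjusted p under 0.05 in limma's moderated test of the 12403 genes with FPKM of at least 1 in at least 2 libraries. The lowest adjusted p was 0.392. At an unadjusted p under 0.05 there were 1201 genes, 473 higher and 728 lower in MBP, where 620.2 would be found by chance alone. With 1 library left out there were 601 (without MBP 1), 712 (without MBP 2), 948 (without control 2) and 2254 (without control 1). Rescaling to TPM changed the split to 533 higher and 507 lower, and the GC and length correction to 423 and 432. On protein-coding genes it was 332 and 831, and at FPKM of at least 5 it was 288 and 573. Of all tested genes 44.8% had groups that did not overlap, where chance gives 33.3%. The count of 0 held in the alternatives fixed before the data were examined. On protein-coding genes only, limma's lowest adjusted p came to 0.0563. The 4 fits chosen after seeing the data that took the spread from recovered reads called 3, 4, 7 and 11 genes in limma, as given under the dependence on processing.

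The genes below are among the 12 with the lowest unadjusted p in each direction, reported as values because none passed. Sdf2l1, a chaperone cofactor of the endoplasmic reticulum (chromosome 16, 17130138 to 17132383, minus strand, GRCm38), had 17.3 ± 0.103 FPKM in controls and 10.9 ± 0.0898 in MBP (SD, n = 2 each), a log2 fold change of -0.62 (SE 0.0526, limma adjusted p = 0.392). Creld2, a secreted stress-responsive protein of the same compartment (chromosome 15, 88819646 to 88826681), had 26.7 ± 0.31 and 18.2 ± 0.0537 FPKM, a log2 fold change of -0.53 (SE 0.0506). Manf, a secreted neurotrophic factor that is also an endoplasmic reticulum stress gene (chromosome 9, 106838312 to 106891979), had 71.0 ± 1.43 and 53.5 ± 2.02 FPKM, and Hyou1, a chaperone (chromosome 9, 44379490 to 44392369), had 75.9 ± 2.66 and 59.4 ± 0.327 FPKM. Socs1, a feedback inhibitor of JAK/STAT signalling (chromosome 16, 10783808 to 10785536), had 5.44 ± 0.173 and 3.60 ± 0.13 FPKM. Ier5l, Hist1h2bn, Id3, Ccdc85b, Tubb3 and Ino80b also belonged here, with log2 fold changes of -0.55, -0.47, -0.51, -0.45, -0.43 and -0.50. Histone genes such as Hist1h2bn have near-identical copies, so its value is uncertain.

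Among genes with higher values, Slc7a11, the cystine transporter subunit (chromosome 3, 49892526 to 50443614), had 7.81 ± 0.0627 FPKM in controls and 9.72 ± 0.119 in MBP (SD, n = 2 each), a log2 fold change of 0.28. Aldh1l2, a mitochondrial enzyme of folate metabolism (chromosome 10, 83487450 to 83534140), had 31.0 ± 0.438 and 36.7 ± 0.278 FPKM, a log2 fold change of 0.24. Cox6a2, Bora, Hnrnpd, Mtx3 and Ifi204 had log2 fold changes of 0.61, 0.26, 0.33, 0.30 and 0.26. The other 5 were the small RNA genes Snora23, Snora30, Snord8, Mir222 and Mir151, at 0.57, 1.02, 1.00, 0.66 and 0.44, on a mean of 93.5, 42.5, 12.2, 58.0 and 14.8 reads. Genes this short can share reads with a longer transcript that overlaps them, so these values are uncertain. Limma's adjusted p for all 12 lay between 0.392 and 0.486.

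The next comparison took the genes of the series title and Gfap, the intermediate filament used as a marker of astrocyte activation. None passed limma's test, and log2 fold changes are given with 95% intervals that do not cover the GC gradient reported below. Akt1, a serine/threonine kinase (chromosome 12, 112653821 to 112674884), had 93.5 ± 5.29 FPKM in controls and 81.9 ± 1.51 in MBP, a log2 fold change of -0.19 (95% interval -0.35 to -0.03, adjusted p = 0.503). Akt2, a related kinase, stood at 0.01 (-0.13 to 0.14). The NF-κB subunits Nfkb1 and Rela stood at -0.05 (-0.19 to 0.09) and 0.02 (-0.14 to 0.19). The IL-6 receptor subunits Il6ra and Il6st stood at 0.05 (-0.13 to 0.23) and 0.07 (-0.08 to 0.22). The kinase Jak2 stood at 0.12 (-0.05 to 0.28) and the transcription factor Stat3 at -0.06 (-0.23 to 0.11). After the GC and length correction Akt1 stood at -0.09, Akt2 at 0.06, Nfkb1 at -0.09, Rela at 0.12, Il6ra at 0.03, Il6st at 0.02, Jak2 at 0.06 and Stat3 at -0.05. The signs of Akt2 and Rela turned when single libraries were left out. These values are transcript levels, and phosphorylation, by which these kinases and factors act, was not measured.

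Il6 and Gfap lay under the filter. Il6 had 0.203 and 0.122 FPKM in the controls and 0.189 and 0.27 in the MBP libraries, from 12, 7, 11 and 17 reads. Gfap had 0.282 and 0.241 FPKM in the controls and 0.218 and 0.119 in the MBP libraries, from 29, 24, 22 and 13 reads. Without the filter their log2 fold changes were 0.08 (limma adjusted p = 0.76) and -0.11 (0.743).

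**Figure D1:**
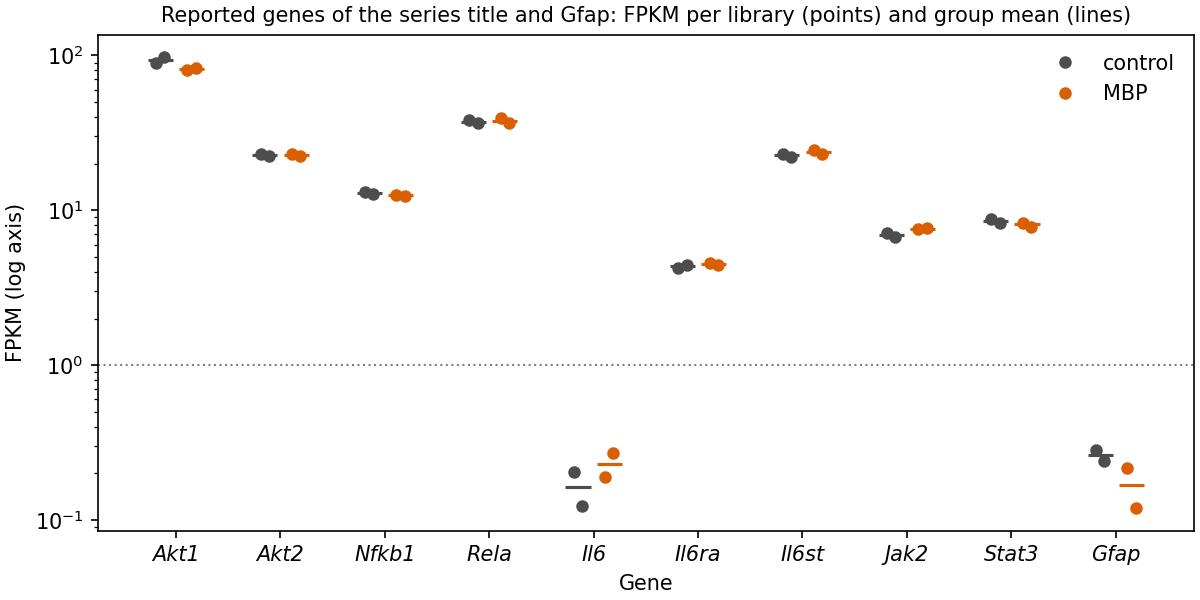
FPKM of the reported genes of the series title and Gfap on a log axis, with 1 point per library, a line at each group mean (2 libraries each) and a dotted line at the filter of 1 FPKM. Il6 and Gfap lie under the filter, and Akt1 has group means of 93.5 in controls and 81.9 in MBP.

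Lists of genes fixed before the data were examined asked whether pathways moved together. The list of the unfolded protein response of the endoplasmic reticulum was lower in MBP, with a median log2 fold change of -0.34 over 15 genes. All 15 had a negative fold change and 13 had groups that did not overlap. In limma's test 0 passed over all genes, and 12 were lower when adjusted over the list alone. Hspa5, the main chaperone of this compartment, had 175.0 and 189.4 FPKM in the controls and 140.2 and 143.6 in the MBP libraries. Xbp1, a transcription factor of this response, had 19.2 and 20.2 in the controls and 13.9 and 16.1 in MBP. Dnajb9 stood at -0.00276 and Sel1l at -0.06. Camera, which compares a list with all other genes, gave an adjusted p of 2.3e-12 with a preset correlation of 0.01. That p takes genes, not libraries, as the units. With an estimated correlation, on 2 residual degrees of freedom, camera did not call the list (unadjusted p = 0.0486, adjusted p = 0.612). The estimated correlation was 0.166 against the preset 0.01, and the degrees of freedom were fewer as well. How much each contributed was not separated.

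Cholesterol synthesis was also lower, with a median log2 fold change of -0.17 over 23 genes, 22 of them negative. In limma's test 0 passed over all genes, and 6 were lower when adjusted over the list alone, among them Fdft1, Hmgcs1, Mvd, Acat2 and Insig1. Hmgcs1, an early enzyme of the pathway, had 17.6 ± 0.134 FPKM in controls and 14.5 ± 0.212 in MBP (SD, n = 2 each). Fdft1, squalene synthase, had 13.5 ± 0.303 and 10.9 ± 0.224 FPKM. Camera gave an adjusted p of 1.68e-09, and 0.612 with an estimated correlation. The list of LXR targets and fatty acid synthesis had a median of -0.12 over 11 genes. Of its 15 members in the table, Abca1, Abcg1, Nr1h3 and Scd1 lay under the filter and were not tested. In control 1, control 2, MBP 1 and MBP 2, Abca1 had 165, 151, 135 and 146 reads and Nr1h3 had 9, 7, 2 and 22. Abcg1 had 0 in each. In limma's test 0 passed over all genes, and 4 were lower when adjusted over the list alone. These were Fasn (55.6 ± 2.11 and 46.1 ± 1.52 FPKM), Acly (43.6 ± 0.0962 and 37.6 ± 0.474), Fads2 (119.4 ± 4.31 and 101.0 ± 1.8) and Nr1h2 (7.90 ± 0.00354 and 6.69 ± 0.0918). Fasn makes fatty acids, Acly supplies their acetyl-CoA, Fads2 desaturates them and Nr1h2 is the receptor LXR beta. Their log2 fold changes were -0.26, -0.21, -0.24 and -0.21, and -0.22, -0.19, -0.18 and -0.10 after the GC and length correction. Camera gave an adjusted p of 0.00101, and 0.612 with an estimated correlation.

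The mitochondrial genome transcripts were higher in MBP, with a median log2 fold change of 0.45 over 7 genes, all positive. In limma's test 0 passed, over all genes or adjusted over the list alone. mt-Nd1 had 2412 and 1949 FPKM in the controls and 3424 and 2659 in the MBP libraries, and mt-Co1 had 6864 and 7800 against 8579 and 7813. Under the filter lay mt-Co2 (9, 6, 9 and 11 reads in control 1, control 2, MBP 1 and MBP 2), mt-Co3 (8, 10, 10 and 7), mt-Atp6 (4, 3, 6 and 6) and mt-Nd4l (1, 5, 4 and 2). These near-empty genes enter the list where no filter is used. They lie on the same genome as mt-Co1, and the reason for so large a gap was not tested. The counting method is not given, so the values of the whole list are uncertain. Camera gave an adjusted p of 0.000678, and 0.857 with an estimated correlation. That call ended without MBP 1 (median 0.28, adjusted p = 0.0765), without the filter (0.374 over 11 genes, 0.0961) and with quantile normalization (0.104, 0.0554).

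**Figure D2:**
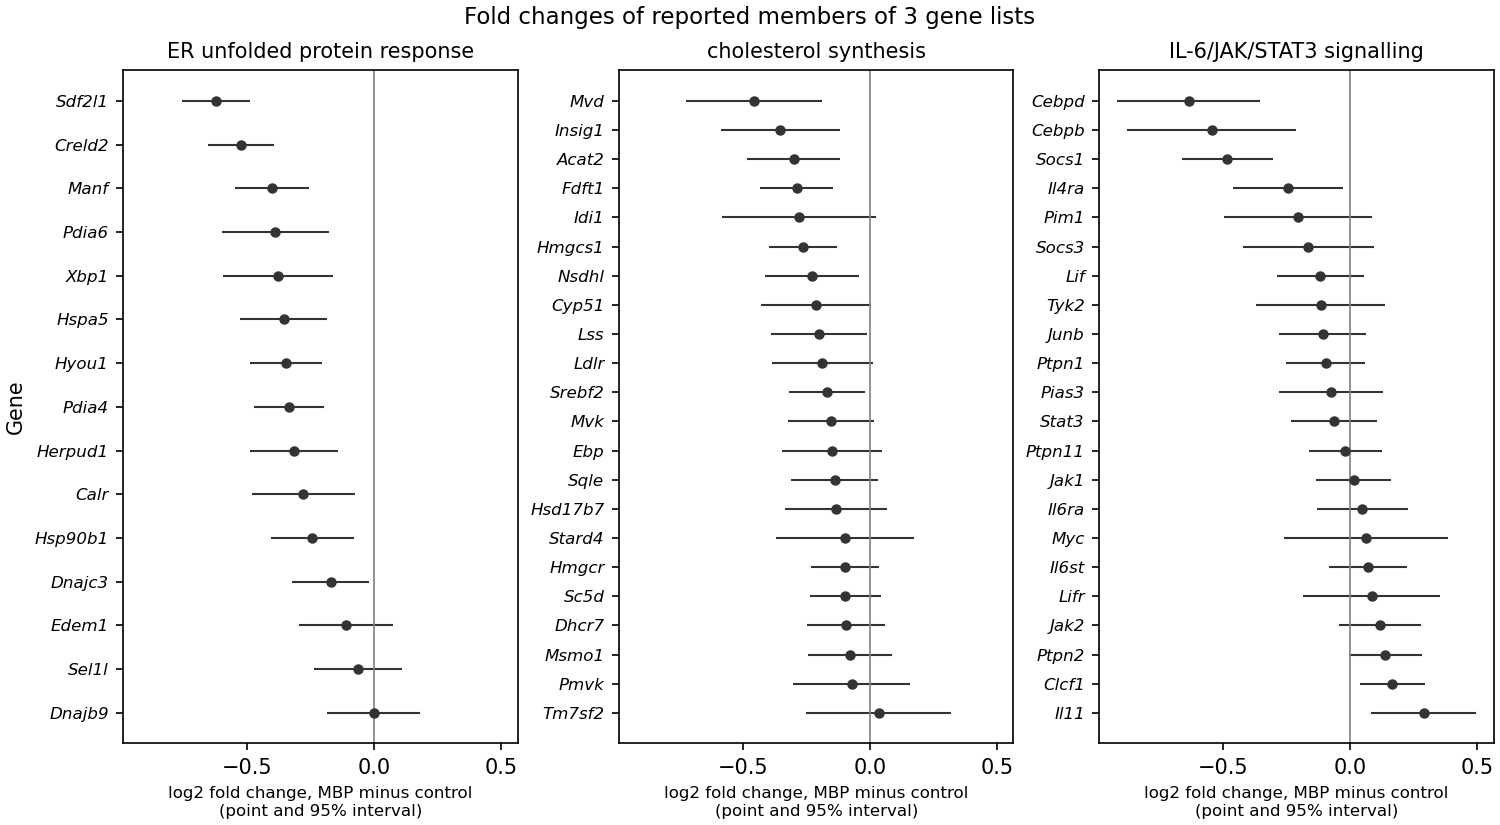
Log2 fold changes (MBP minus control) of reported members of 3 lists, as points with 95% intervals from limma. All 15 members of the unfolded protein response list and all but 1 of the plotted cholesterol synthesis genes lie under 0, while the IL-6/JAK/STAT3 list has 9 genes above and 13 under 0.

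The lists of the pathways in the title did not pass. IL-6/JAK/STAT3 signalling had a median log2 fold change of -0.07 over 22 genes (camera adjusted p = 0.41). In limma's test 0 of its genes passed over all genes, and 2 were lower when adjusted over the list alone: Socs1 and Cebpd, a transcription factor at 2.33 ± 0.219 and 1.14 ± 0.111 FPKM. Il11, a cytokine of the IL-6 family, had 5.17 ± 0.0426 and 6.56 ± 0.617 FPKM. NF-κB subunits and targets had a median of -0.03 over 20 genes (adjusted p = 0.676), and the chemokine Ccl2 had 29.6 and 33.2 FPKM in controls and 23.6 and 27.4 in MBP. The PI3K/AKT pathway had a median of 0.01 over 28 genes (adjusted p = 0.676). In both lists 0 genes passed, over all genes or adjusted over the list alone.

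Lists of astrocyte states did not pass camera either. Fry's mixed test, which asks for change in either direction, called 2 of them, pan-reactive (adjusted p = 0.016) and A2 (0.0469), while its directional test called 0. Astrocyte identity had a median of -0.02 over 10 genes (camera adjusted p = 0.978), with Vim, which many cell types express, at 530 ± 1.92 and 494 ± 9.49 FPKM. The table held 21 members of this list, and those under the filter included Slc1a3 (0, 0, 0 and 1 reads in control 1, control 2, MBP 1 and MBP 2), Gja1 (3, 5, 12 and 8), Aldh1l1 (9, 12, 6 and 7) and Slc1a2 (61, 55, 63 and 70). Pan-reactive genes had a median of 0.05 over 6 (adjusted p = 0.634), among them the adhesion receptor Cd44 at 83.7 ± 1.67 and 93.3 ± 1.23 FPKM. A1 genes had a median of -0.04 and a mean of 0.000701 over 4 (adjusted p = 0.978). A2 genes had a median of 0.10 over 5 (adjusted p = 0.41), with Clcf1 at 22.6 ± 0.296 and 25.5 ± 0.0445 FPKM. The table held 10 pan-reactive, 12 A1 and 10 A2 members, and those under the filter were not tested. Among them were the A1 gene C3 (1, 5, 3 and 3 reads, in the same order of libraries) and the pan-reactive gene Lcn2 (1, 3, 3 and 1). These list results do not cover them. Synapse-forming factors made by astrocytes had a median of -0.03 over 18 (adjusted p = 0.568), with Thbs1 at 99.9 and 101.7 FPKM in controls and 96.0 and 86.7 in MBP. In these lists 0 genes passed limma's test, over all genes or adjusted over the list alone.

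For the remaining lists camera's adjusted p was 0.138 or above and 0 genes passed limma's test over all genes. Medians were -0.08 for PPAR targets (20 genes), -0.02 for NRF2 antioxidant genes (20), -0.01 for the ATF4 stress response (20, with the test pointing up), -0.05 for cell division (30), -0.01 for p53 targets (12), 0.02 for the interferon response (12), -0.08 for hypoxia and glycolysis (16), -0.01 for extracellular matrix (16), 0.10 for immediate early genes (12) and -0.08 for AhR targets (4). Among markers of other cell types, medians were -0.10 for microglia and macrophages (3 genes), -0.12 for the oligodendrocyte lineage (4), -0.04 for neurons (6) and -0.14 for fibroblasts and pericytes (4). Sox10, a marker of the oligodendrocyte lineage, stood at 98.1 ± 2.71 FPKM in controls and 88.7 ± 1.34 in MBP, a log2 fold change of -0.14, and of -0.04 after the GC and length correction. The neuron marker Tubb3 was the 1 gene of these lists lower when adjusted over the list alone. The endothelial list had 1 tested gene, Flt1, at 0.05, and was only described.

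Fold changes followed the GC content of the transcript. Across 12389 genes, which are not independent replicates, Spearman's rho of log2 fold change with GC content was -0.442. It was 0.139 for control 2 minus control 1 and -0.158 for MBP 2 minus MBP 1. Median log2 fold changes ran from 0.08 in the eighth of genes with the lowest GC content to -0.09 in the eighth with the highest. After a correction for GC content and length, chosen after seeing the data, camera's adjusted p was 5.35e-17 for the unfolded protein response, 4.22e-11 for cholesterol synthesis, 0.000805 for LXR targets and fatty acid synthesis and 0.00318 for mitochondrial transcripts. These use the preset correlation. With an estimated correlation, and without the GC correction, adjusted p was 0.612 for the first 3 and 0.857 for mitochondrial transcripts.

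**Figure D3:**
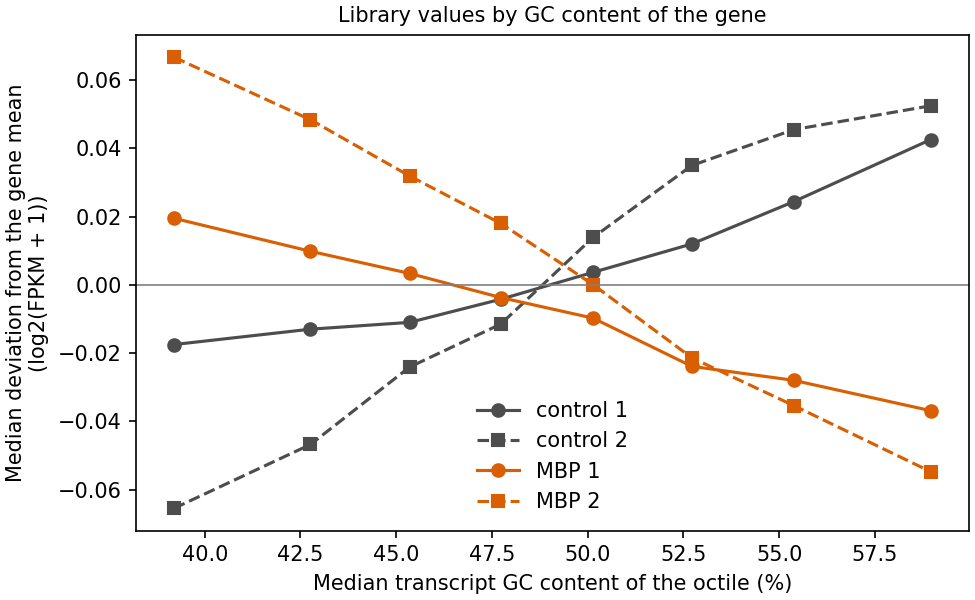
Median deviation of each library from the gene mean, on the log2(FPKM + 1) scale, in 8 equal groups of genes ordered by transcript GC content (%). Both controls rise with GC content, control 2 from -0.07 to 0.05, and both MBP libraries decline, MBP 2 from 0.07 to -0.05.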

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

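The GC and length corrections, the spread trend on recovered reads and both limma-voom fits were chosen after the results were seen, and the 4 that model the spread from reads were run on a main count of 0. Genes changed by MBP stayed at 0 in the alternatives fixed before the data were examined and with both GC corrections. The 2-fold threshold picks among genes already called, so its 0 followed from the main count and was no check. Genes changed by MBP became 3 with the spread trend on recovered reads and 4 with that trend on protein-coding genes. They became 11 with voom on recovered reads and 7 with voom on protein-coding genes of at least 50 reads. These came to 11 genes in all, and 3 were called in all 4 of these fits: Creld2, Sdf2l1 and Ier5l, each lower. The prior degrees of freedom, the weight limma gives to the spread shared over genes, were 3.06 in the main fit. In these fits they were 8.88, 9.41, 13.2 and 12.6, in the order given. Sdf2l1 had a log2 fold change of -0.623 in the main fit and in both spread-trend fits. Its SE was larger in those (0.0807 and 0.0804) than in the main fit (0.0526), so a larger effect was not what made its call there. Genes at an unadjusted p under 0.05 numbered 601 to 2254 when 1 library was left out (601 without MBP 1, 712 without MBP 2, 2254 without control 1) and 855 with the GC correction. On protein-coding genes they numbered 1163, and 765 with the GC correction. Where a library is left out, the lone sample is assumed to vary like the other group.

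The 3 lower lists kept their direction and their call in all 20 camera alternatives with the preset correlation (the robust spread does not enter camera), with adjusted p from 3.98e-19 to 6.68e-08 for the unfolded protein response, 2.42e-12 to 2.98e-05 for cholesterol synthesis and 0.000506 to 0.034 for LXR targets and fatty acid synthesis. Some of the 20 are repeats. Camera with the robust spread is the main run again. With the spread trend on recovered reads it is the main or the protein-coding run on nearly the same genes. The number of lists called fell from 4 to 0 with an estimated correlation and with fry's directional test. Adjusted p was then 0.612 for those 3 lists and 0.857 for mitochondrial transcripts by camera, and 0.117, 0.198, 0.117 and 0.343 by fry for the unfolded protein response, cholesterol synthesis, LXR and mitochondrial lists. Fry's mixed test gave 0.0514 for cholesterol synthesis and 0.187 for mitochondrial transcripts. It called 4 lists: the unfolded protein response (0.022) and LXR (0.016), which camera also called, and pan-reactive (0.016) and A2 reactive astrocytes (0.0469), which it did not. Mitochondrial transcripts stayed higher but lost their call with no filter (0.0961) and quantile normalization (0.0554), and ran from 3.68e-05 to 0.0765 with 1 library left out. Their median log2 fold change, 0.452 in the main analysis, was 0.374 with no filter, 0.104 with quantile normalization, 0.367 with the GC correction and 0.254 to 0.63 with 1 library left out. Immediate early genes were called higher with GC correction (0.0394), on protein-coding genes with it (0.00322) and without MBP 2 (0.0035). Oligodendrocyte lineage markers were called lower without control 2 (0.0322). With an estimated correlation in the main analysis, camera's adjusted p was 0.857 for both immediate early genes and oligodendrocyte lineage markers. Fry's directional test gave 0.836 and 0.343. The cause was not tested. The ratio of distances between and within groups ran from 1.03 to 1.13.

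Of 124 named genes, 110 kept their direction in every alternative that tested them. None of the other 14 was called. With 1 library left out, log2 fold changes ran from -0.0144 to 0.0307 for Akt2, -0.0329 to 0.0784 for Rela, -0.105 to 0.0637 for Cd68, -0.00559 to 0.0523 for Col3a1, -0.0922 to 0.331 for Cyr61, -0.0152 to 0.211 for Emp1, -0.0459 to 0.0627 for Fkbp5, -0.0102 to 0.12 for Flt1, -0.229 to 0.0682 for Ggta1, -0.0032 to 0.187 for Map2, -0.165 to 0.108 for Nqo1, -0.167 to 0.0957 for Olig2 and -0.0331 to 0.0909 for Tiparp. With GC correction, and then on protein-coding genes with it, they were 0.0681 and 0.0819 for Cd68, 0.00416 and 0.00641 for H2-D1, 0.000647 and 0.0219 for Nqo1, 0.0563 and 0.0577 for Olig2, and -0.0435 and -0.0354 for Tiparp.

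No paired analysis was possible because the titles of the 2 groups share a single number. A fit on transcript rows was not run, since the rows are genes, and neither were edgeR and DESeq2, which were set for a table of raw counts and were not run on the recovered reads. Il6 and Gfap rest on 7 to 29 reads per library.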

Other observations

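Tests of the GC gradient, of the GC and length correction on the lists and of GO terms were chosen after the results were seen. Leaving out libraries, the other splits and the residual of TEC genes were written down before those values were seen, though library values of the leading single genes had been. Outside the lists, GO terms carried by the table were tested with camera (1365 terms of 10 to 300 genes). The 1 term called was the cholesterol biosynthetic process, lower over 22 genes (adjusted p = 0.000857, and 0.000437 after the GC correction), and 0 were called with an estimated correlation. It shares genes with the cholesterol list and is not independent of it. Response to endoplasmic reticulum stress, a wider set of 60 genes, had a median of -0.04 and was not called (adjusted p = 0.261). Nor was the term for the unfolded protein response of the endoplasmic reticulum, with a median of -0.04 over 40 genes (adjusted p = 0.9, and 0.997 after the GC correction).

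The 15-gene list of the unfolded protein response and the list of cholesterol synthesis had lower medians in MBP libraries. Camera called both at the preset correlation only: adjusted p was 0.612 for both with an estimated correlation, and 0.117 and 0.198 with fry's directional test. The GC and length gradient alone does not account for them. After its removal the medians were -0.311 (SE 0.036) and -0.158 (SE 0.0359), where the gradient as cause would leave -0.1 or above, a bound written after the results were seen. These SEs are over the genes of a list, which are not independent replicates, and do not measure the spread between libraries. The cholesterol median lies closer to the bound. A single library does not account for them either, since the weakest medians with 1 library left out were -0.312 and -0.122. The 4 libraries make 3 splits, too few for a share under 0.05. In 1 of the 3, the real one, the mean was as far from 0 (-0.303 and -0.194), and the highest of the other splits was 0.0386 and 0.0455. Both lists were picked because they were lower in the real split, so a larger mean there was to be had from the choice and is no support. The treatment may lower these genes, but the handling of the cultures was not separated from it and 2 libraries per group leave this a hypothesis.

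GC-rich genes were lower in MBP libraries. Transcript length does not explain this, since the partial rank correlation with GC content at fixed length was -0.426. GC bias of single libraries cannot be told apart from an effect of the group: the slope of the difference between groups was 2.47 times the larger of the 2 within groups, but 2 against 2 libraries allow no exact p under 0.333, too few to decide. A difference in library preparation between the groups could give such a slope, as could the treatment, and neither was tested.

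Genes of the biotype TEC, transcribed regions without an experimentally established gene model, were higher in MBP libraries, with a median log2 fold change of 0.14. The GC gradient of protein-coding genes does not explain this, as the median residual from that trend was 0.139 (SE 0.00797) over 610 genes. Control 2 had the lowest median deviation, at -0.141, against 0.00459 in control 1, 0.0458 in MBP 1 and 0.0888 in MBP 2. The median was 0.0683 without control 2 and 0.218 without control 1, 0.162 without MBP 1 and 0.113 without MBP 2, so much of the difference may come from control 2. No biological explanation was tested.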
